A study of Mus musculus with 12 samples.

How the data were processed

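Total RNA from whole tumours was isolated with Triazol, labelled with biotin by in vitro transcription and hybridized to 12 Affymetrix expression arrays for mouse transcripts, per the labels' protocols. The authors deposited 1 table of log2 expression values, 1 per probe set and array, given to 2 decimals. The log2 scale and a normalization between arrays were read from the deposited values, which run from 1.62 to 13.88 with near-equal quantiles on all arrays, and the method of background correction, normalization and summarization is not given in the sources used here. No pair of arrays was identical (0 pairs), their correlations lay between 0.959 and 0.997, and no column was left unused (0). Arrays were grouped by line and antibody from the sample titles, 3 per group.

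Of 45101 probe sets, 64 controls were set aside, 34945 carried 1 gene, 932 several genes and 9160 none. Only those with 1 gene were used, and 34741 of their symbols were found by gene number in a mouse gene table of assembly GRCm38.p6, which also gave the chromosomes and the order of the genes around Cdkn2a. Of 18193 genes named, 8534 had several probe sets, and the probe set with the highest mean over all arrays stood for its gene. Genes were kept where at least 3 arrays exceeded the 25th percentile of all values (3.32), which left 15493.

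Differences were tested with limma 3.58.1 in R 4.3.3, with 1 mean per group over all 12 arrays, 8 residual and 2.98 prior degrees of freedom, and 5 contrasts: resistant against parental under each antibody, anti-PD-1 against IgG in each line, and the interaction. The p-values are two-sided, adjusted by Benjamini-Hochberg within a contrast and called under 0.05. Contrasts that share a group share its chance values, while the comparisons of the lines under each antibody share no array. The median standard error of a difference was 0.117, and 0.166 for the interaction. Single values such as list means were compared by exact permutation tests, which with 3 arrays against 3 cannot give a p under 0.1. No depth can be given for arrays, so their number limits the precision. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

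The 31 gene lists, with 604 entries of which 553 matched a tested gene, cover fatty acid binding proteins, lipid use, ferroptosis, metabolism, cell cycle, immune and stromal cell types, host tissues, lung and epithelial lineage, Y-linked genes and signalling targets. They were tested with camera (preset correlation of 0.01), which compares a list with all other genes, with camera and a correlation estimated from the arrays, and with fry, and p-values were adjusted over the 31 lists. The estimated correlations ran from -0.282 for red blood cells to 0.916 for interferon gamma, with 0.885 for cell cycle and 0.805 for skeletal muscle. Where they lie far above the preset, the p-values with the preset are too small. Lists called higher or lower below are so by the preset test. Genes were also counted with p-values adjusted over a list alone. A list of 32 immediate early genes and one of 76 mitochondrial ribosomal protein genes were added after the results were seen and are reported only in the closing section.

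In each contrast the named genes were the 10 highest and 10 lowest differences among called genes whose groups did not overlap, passing over predicted genes, clones and receptor segments of B and T cells. To these were added all 7 tested fatty acid binding protein genes, Pdcd1, Cd274, Gpx4, Slc7a11 and Acsl4, and examples from the 4 members with the smallest p in a list described. Where fewer than 3 genes passed, the 3 smallest p-values in each direction were named. Mtap, Xist and the neighbours of Cdkn2a are exceptions, chosen after their values were seen. Among called genes with further probe sets, a probe set pointed the other way for 320 of 1360 between the lines under IgG, 75 of 306 for anti-PD-1 in parental tumours and 795 of 2786 between the lines under anti-PD-1. Among the fixed genes not called this held for Slc7a11 between the lines under IgG, Fabp3, Gpx4 and Acsl4 for anti-PD-1 in parental tumours and Acsl4 in resistant tumours. It also held for Fabp3 and Fabp4 between the lines under anti-PD-1 and for Fabp3, Fabp5, Gpx4 and Acsl4 in the interaction.

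The fit was tested on simulated data with 15493 genes, each drawn independently with its real mean and residual SD, and with 67, 67 and 66 genes changed by 1.5, 2 and 4-fold. The simulation holds no correlation between genes and no arrays that stand apart, both found in the real data. Its rates therefore test the code and do not give the error rates of the comparisons below. At 1.5, 2 and 4-fold it recovered 59.7%, 89.6% and 98.5% of changed genes for the lines under IgG, 65.7%, 88.1% and 98.5% for anti-PD-1 in parental tumours, 67.2%, 88.1% and 95.5% for anti-PD-1 in resistant tumours and 49.3%, 88.1% and 97.0% for the lines under anti-PD-1, with 7, 7, 4 and 5 false calls.

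The arrays of every group are numbered 1 to 3, and the labels do not say that equal numbers mark the same animal, batch or day. Deviations of same-numbered arrays from their group means correlated at 0.113, 0.123 and 0.174 between the resistant groups, above 0.1 for each of the 3 pairs, so the fit with the replicate number as a block stands beside that comparison. For the other comparisons at least 1 pair fell below 0.1 (0.057, -0.208 and 0.093 at the lowest). The other pairs of the parental groups correlated at 0.636 and 0.44, more than any pair of the resistant groups, so a shared factor is not excluded there.

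Alternatives were quantile normalization, centring each array on its median, no filter, a filter at the median, the mean of a gene's probe sets, every probe set on its own, only the compared groups, limma with trend and robust, array weights, the replicate block, a change of at least 2-fold and leaving out each array in turn. With every probe set on its own, a named gene was read from its probe set with the smallest p. Each array was left out only in the contrasts that use its group. After the data were seen, fits without the pair of parental arrays that stood apart and with the skeletal muscle list as a covariate were added. Alternatives for a pseudocount were not run, since the values are already log2.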

Results

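RNA from whole subcutaneous tumours of female 129sv/ev mice was measured on 12 Affymetrix expression arrays for mouse transcripts, 3 in each of 4 groups. The tumours grew from 344SQ cells, a mouse lung adenocarcinoma line, and came either from the parental line or from a derivative resistant to anti-PD-1, an antibody that blocks an inhibitory receptor of T cells. Mice received control IgG or anti-PD-1 at 10 mg/kg on days 4 and 7 after inoculation, and the tumours were collected on day 11. The labels give 5 mice per group and 3 arrays per group but not which mice lie behind an array, so the p-values measure only the spread between these arrays, and the number of arrays limits the precision. Values are log2 expression levels, with array lower quartiles between 3.27 and 3.36. Differences are given on the log2 scale with the adjusted p of limma over the 15493 genes tested. The comparisons, the 31 gene lists and the rule for naming genes were fixed before the data were examined.

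Tissue content and RNA quality varied between the arrays as well as between the groups. On the first principal components, with 48.5% and 21.6% of the variance, control IgG replicate 1 and anti-PD-1 replicate 3 of the parental tumours stood apart from the other arrays. The mean level of the skeletal muscle list was 8.64 ± 2.01 (SD, n = 3) in parental tumours given IgG, 9.84 ± 0.94 in parental tumours given anti-PD-1, 9.05 ± 0.34 in resistant tumours given IgG and 7.64 ± 1.30 in resistant tumours given anti-PD-1. The Gapdh control probe sets for the 3' end exceeded those for the 5' end by 0.26 ± 0.10 in the 6 parental arrays and by 0.035 ± 0.052 in the 6 resistant arrays (exact permutation test, two-sided p = 0.00216, the smallest it can give). The corresponding actin values were 0.75 ± 0.11 and 0.48 ± 0.08 (exact p = 0.00216).

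**Figure D1:**
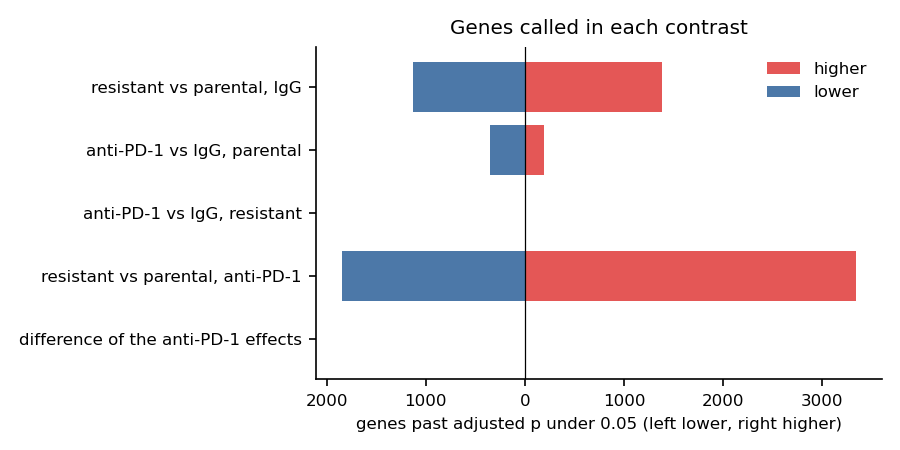
Number of genes past an adjusted p of 0.05 in each comparison, lower to the left and higher to the right of 0. The bars run to 1133 lower and 1384 higher genes between the lines under control IgG, to 351 and 191 for anti-PD-1 in parental tumours, to 0 for anti-PD-1 in resistant tumours and for the interaction, and to 1843 and 3343 between the lines under anti-PD-1.

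Resistant and parental tumours given control IgG were compared to ask how the lines differ without the treatment. Cdkn2a and Cdkn2b, neighbouring genes on chromosome 4 that encode inhibitors of the cell cycle, were far lower in resistant tumours. Cdkn2a was at 3.29 ± 0.56 against 7.02 ± 0.22 (SD, n = 3), a difference of -3.73 (SE 0.25, adjusted p = 2.9e-05), and Cdkn2b differed by -3.34 (adjusted p = 0.000157). Also lower were the chloride channel gene Cftr at -5.00 (SE 0.40, adjusted p = 6.31e-05) and the transcription factor gene Ehf at -4.08 (SE 0.23, adjusted p = 6.82e-06). The tight junction gene Cldn9 was higher by 3.45 (SE 0.31, adjusted p = 0.000134), and Ambp, the gene of a secreted plasma protein precursor, by 2.63 (SE 0.22, adjusted p = 0.00011). In all, 1384 genes were higher and 1133 lower in resistant tumours, 182 and 186 of them by at least 2-fold.

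Further genes with large differences under control IgG included Y-linked genes. The Y-linked genes Eif2s3y, Kdm5d and Uty were lower at -5.01, -4.20 and -2.05, with adjusted p-values of 3.09e-08, 4.38e-06 and 3.6e-05. Also lower were Afp, the gene of alpha-fetoprotein (-4.01, with another of its probe sets pointing the other way), the calcium channel gene Cacna1h (-3.33), the interferon-induced GTPase gene Gbp8 (-3.33) and the granzyme gene Gzmg (-3.25). Higher genes included Adipoq, a hormone gene of adipocytes (3.99), Sln, a regulator of the muscle calcium pump (3.79), the haptoglobin gene Hp (3.56), Sfrp2, a secreted Wnt antagonist (3.39), Dynap (2.59), Lyve1, a hyaluronan receptor of lymphatic endothelium and some macrophages (2.39), Efemp1 (2.33) and Mgp (2.32), both of the extracellular matrix. Non-overlap of the lines' arrays was a condition for naming these genes. The mean of the adipocyte list was 5.84 ± 0.95 in these resistant tumours and 4.72 ± 0.19 in the parental ones, and the Gapdh difference between the ends was 0.037 ± 0.061 and 0.21 ± 0.08.

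**Figure D2:**
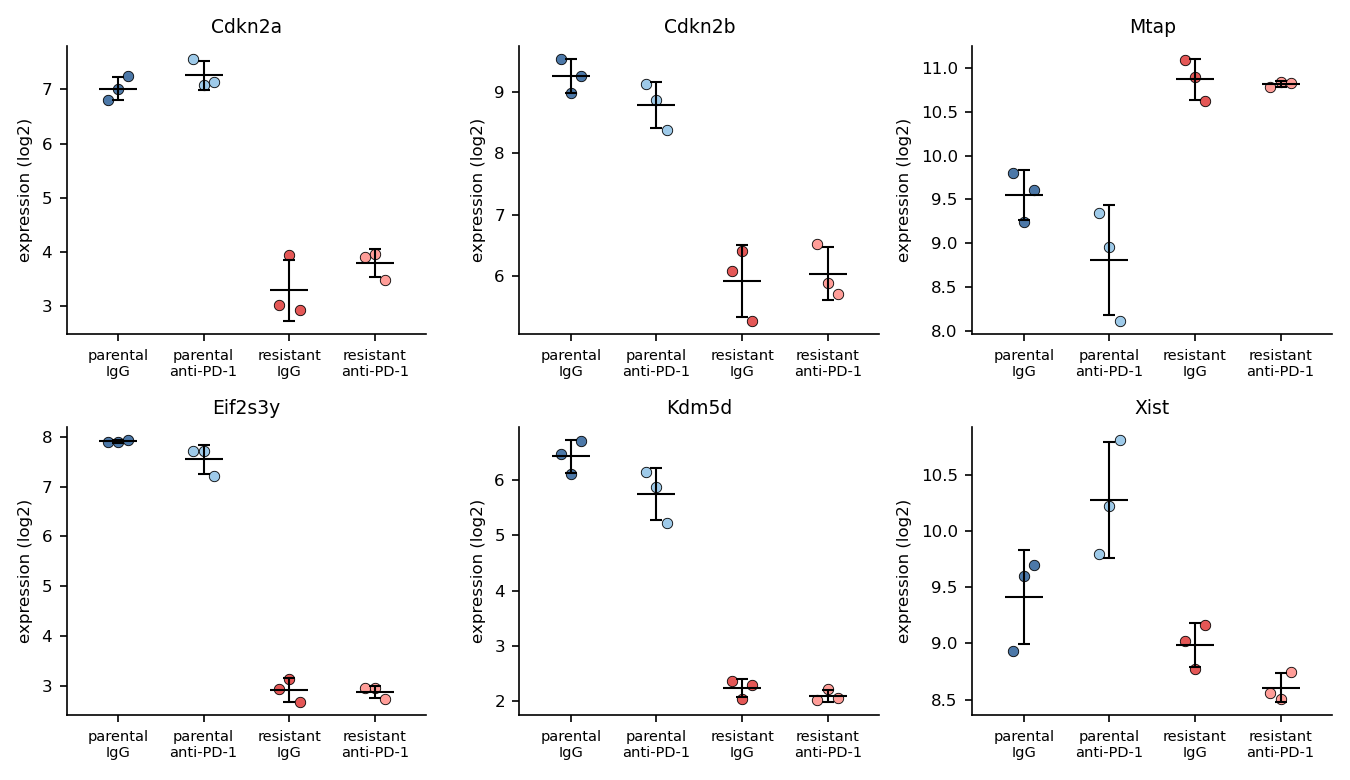
Log2 expression of Cdkn2a, Cdkn2b, Mtap, Eif2s3y, Kdm5d and Xist on each array, by group; points are arrays, the dash is the mean and the bar the SD (n = 3). Cdkn2a averaged 7.02 and 7.26 in parental and 3.29 and 3.79 in resistant tumours, while Mtap, chosen with Xist after the values were seen and next to it on chromosome 4, averaged 9.55 and 8.80 in parental and 10.88 and 10.82 in resistant tumours.

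Of the 7 fatty acid binding protein genes tested, which encode carriers of fatty acids within cells, Fabp5 was lower in resistant tumours given IgG. Its level was 9.78 ± 0.38 against 10.89 ± 0.10, a difference of -1.11 (SE 0.20, adjusted p = 0.00444). Fabp4, the carrier abundant in adipocytes and macrophages, was at 10.40 ± 1.25 against 7.60 ± 1.98 (2.80, SE 0.95, adjusted p = 0.0673), short of the threshold. Its parental values were 5.33, 8.95 and 8.53, the low one from replicate 1, which stood apart. Adjusted over the list alone 1 gene was higher and 1 lower. The remaining members did not pass, with 1.24 for Fabp7, 0.44 for Fabp3, 0.13 for Fabp6, 0.010 for Fabp12 and 0.013 for Pmp2. The list as a whole had a median of 0.13 and an adjusted p of 0.937 by camera. Among the genes of the checkpoint and of ferroptosis, a death by lipid peroxidation, Acsl4, which loads polyunsaturated fatty acids for membrane lipids, fell by 0.50 (adjusted p = 0.0166), a call lost without parental IgG replicate 3 (-0.46) or resistant IgG replicate 2 (-0.42). Cd274, the gene of PD-L1, differed by -1.44 (adjusted p = 0.0968), Pdcd1 by -0.28 (0.507), the lipid peroxide reductase gene Gpx4 by 0.21 (0.119) and the cystine transporter gene Slc7a11 by -0.060 (0.904).

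Ferroptosis genes differed in both directions between the lines under control IgG, while the fatty acid oxidation and cell cycle lists were higher in resistant tumours. In the ferroptosis defence list 3 of 21 genes were higher and 3 lower, or 4 and 3 adjusted over the list alone (list adjusted p = 0.487). Examples are Hspb1 at 1.22, Gch1 at 0.76, Mboat2 at -0.95 and Gclc at -0.69. Of 23 ferroptosis drivers and markers 4 were higher and 5 lower, or 7 and 9 adjusted over the list alone, among them Lpcat3 at -0.72, Tfrc at -0.63 (another probe set pointed the other way) and Pebp1 at 0.35. That list had a median of 0.037, a mean of -0.040 and an adjusted p of 0.373. Fatty acid oxidation genes were higher as a list (median 0.30, adjusted p = 0.0219, and adjusted p = 0.715 with an estimated correlation). Of its 19 genes 6 were higher, 8 adjusted over the list alone, including Cpt2 at 0.45 and Hadha at 0.36. Cell cycle genes were higher with all 26 members positive (median 0.57, adjusted p = 0.000924, and adjusted p = 0.715 with an estimated correlation). Of these 4 were called, also 4 adjusted over the list alone, including Mcm5 at 1.18 and Pcna at 0.42. Lipid uptake and droplets (median 0.37, adjusted p = 0.116), fatty acid and sterol synthesis (-0.11, 0.0819), oxidative phosphorylation (0.053, 0.876), and hypoxia and glycolysis (-0.13, 0.236) did not pass as lists. Called members included Plin2 (0.60), Me1 (-0.85), Cox4i1 (0.34), Car9 (1.33) and Hk2 (-0.90).

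Interferon, cytotoxic cell and mast cell lists were lower in resistant tumours given IgG, and the other immune lists did not pass. All 29 genes of the interferon gamma and antigen presentation list were negative, with a median of -1.72. Of these 4 were called, Cd74 (-1.67), Gbp3 (-3.31), Gbp6 (-3.54) and Irgm1 (-2.01), and 24 were lower adjusted over the list alone. The list had an adjusted p of 4.36e-10 by camera, an adjusted p = 0.715 with an estimated correlation and 0.149 by fry. The mean of this list differed by -1.90 in the tumours given IgG, with arrays that overlapped (exact permutation test, p = 0.2, the smallest possible being 0.1), and by -2.00 over all 6 resistant and 6 parental arrays (exact p = 0.00866). Type I interferon genes (median -0.65, 1 of 25 called, Ifit2 at -1.57), cytotoxic T and NK cell genes (-0.46, 2 of 24 called, Gzmb at -2.16 and Gzmc at -1.48) and mast cell genes (-0.58, 0 of 9 called, all but 1 negative) were lower as lists, with adjusted p-values of 5.05e-05, 0.00762 and 0.015, and adjusted p = 0.715 for each with an estimated correlation. None of these 3 lists had a call adjusted over the list alone. Immune checkpoint genes (median -0.14, adjusted p = 0.102), CD4 and regulatory T cells (-0.055, 0.333), B and plasma cells (0.22, 0.271), macrophages and monocytes (0.11, 0.271), neutrophils (0.45, 0.269) and dendritic cells (0.16, with a mean of -0.001, 0.931) did not pass. Called members included Cd163 (1.83), Pf4 (1.38), Lyve1 (2.39), Pdcd1lg2 (-0.66) and Itgax (-1.07).

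Stromal lists were higher and lineage lists lower. Fibroblast and matrix genes (median 0.61, 5 of 23 called, 6 adjusted over the list alone), endothelial genes (0.62, 5 of 20 called, 12 higher and 2 lower adjusted over the list alone) and adipocyte genes (1.03, all 15 positive, 3 called, 4 adjusted over the list alone) had adjusted p-values of 0.0219, 0.00893 and 0.00618, and adjusted p = 0.715 for each with an estimated correlation. The adipocyte median was 0.37 without resistant IgG replicate 2. Examples are Mfap5 at 1.72, Sparc at 0.94, the endothelial receptor gene Aplnr at 1.55, Emcn at 1.59, Pparg at 0.76 and Sncg at 1.55. Lung lineage genes were lower (median -0.14, 5 of 15 called lower, 5 lower and 1 higher adjusted over the list alone, adjusted p = 0.0166), with the surfactant protein gene Sftpd at -1.73 and the lipid transporter gene Abca3 at -0.85. Epithelial tumour cell genes were lower too (-0.23, 3 of 18 lower and 1 higher, also adjusted over the list alone, 0.0193), with the tight junction gene Ocln at -2.97, Epcam at -1.54 and Cldn6 at 1.49. With an estimated correlation these had adjusted p = 0.261 and adjusted p = 0.715. The 3 Y-linked genes were lower as a list (median -4.20, adjusted p = 1.75e-08, and adjusted p = 0.0713 with an estimated correlation). Skeletal muscle (0.51, adjusted p = 0.943), keratinocytes (0.18, 0.271), nerve (0.097, 0.271), red blood cells (0.25, 0.487), mesenchymal state (0.30, 0.271) and TGF-beta, Wnt and Notch targets (0.12, 0.271) did not pass. Called members included Id3 (2.20), Cdh2 (-0.93), Scn7a (2.09) and Krt14 (1.64).

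The comparison between the lines under control IgG called 2517 genes, and 5122 (33.1%) had an unadjusted p under 0.05. The arrays of the lines did not overlap for 6019 genes (38.8%, against 10% by chance), 2500 of them called. Leaving out parental IgG replicate 2 or 3 gave 1542 or 1569 genes and leaving out resistant IgG replicate 1 or 2 gave 1472 (730 higher and 742 lower) or 1273, while array weights gave 5152. Of the 63 named genes called, 32 kept the call whichever array was left out. Among the lists, single arrays ended the calls of fibroblasts (median 0.50 or 0.54 without parental IgG replicate 1 or 3, 0.45 without resistant IgG replicate 3), endothelial cells (0.48 without parental IgG replicate 1, 0.56 without resistant IgG replicate 3) and fatty acid oxidation (0.22 without parental IgG replicate 1, 0.30 or 0.22 without resistant IgG replicate 1 or 2). They also ended those of mast cells (-0.27 or -0.54 without parental IgG replicate 2 or 3), epithelial tumour cells (-0.097 without parental IgG replicate 1) and cytotoxic cells (-0.21 without parental IgG replicate 3). Centring each array on its median moved the split to 2100 higher and 881 lower genes. Resistant levels of Eif2s3y, Cftr, Kdm5d, Cdkn2a and Gzmg (2.91, 2.80, 2.23, 3.29 and 2.57) lay below the dim filter of 3.32, so the size of their differences is a lower limit.

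Parental tumours given anti-PD-1 were compared with those given IgG to ask what the treatment changed in the line that was not selected for resistance. Fosb, a member of the AP-1 family of early response transcription factors, rose from 5.02 ± 0.23 to 7.74 ± 0.61 (SD, n = 3), by 2.72 (SE 0.31, adjusted p = 0.0123). The stress response factor gene Atf3 rose by 1.56 (SE 0.19, adjusted p = 0.0123), the cytokine gene Il6 by 2.29 (SE 0.47, adjusted p = 0.034) and Ptgs2, which encodes an inducible prostaglandin synthase, by 1.19 (SE 0.16, adjusted p = 0.0123). Among lower genes, Cftr fell by 1.74 (adjusted p = 0.0406, and by 1.14 without parental anti-PD-1 replicate 3), the glutathione peroxidase gene Gpx2 by 1.69 (adjusted p = 0.0381) and Ddc, the gene of aromatic amino acid decarboxylase, by 1.43 (adjusted p = 0.0123). Of the genes named so far for this comparison only Fosb kept its call whichever array was left out. In all, 191 genes were higher and 351 lower, 31 and 19 of them by at least 2-fold.

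Other genes were also among the largest changes in parental tumours. Myog, a muscle transcription factor gene, rose by 2.14, Myl4 by 2.19 (with another probe set pointing the other way), Chrna1, a subunit of the muscle acetylcholine receptor, by 1.40, Cilp by 1.68, Pi16 by 1.38, the growth factor gene Igf2 by 1.39 and Nav2 by 1.43. Lower genes further included Slc16a12 (-1.58), Kcne3 (-1.52), Aadac (-1.43), Sult1c2 (-1.37), Ly6k (-1.27), Mia (-1.25) and the gastrokine gene Gkn2 (-1.23). The skeletal muscle list was higher in these tumours (median 1.26, all 19 genes positive, 0 called by limma, adjusted p = 0.00246, and adjusted p = 0.655 with an estimated correlation), but its median was -0.088 without parental IgG replicate 1, 0.75 and not past the threshold without parental anti-PD-1 replicate 3, and -0.56 without both arrays that stood apart.

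Immune lists other than B and plasma cells and mast cells were higher in parental tumours given anti-PD-1, with few single genes past the test. The interferon gamma and antigen presentation list had a median of 0.91 with all 29 genes positive (adjusted p = 5.49e-05, and adjusted p = 0.655 with an estimated correlation). None was called (0, also 0 adjusted over the list alone), with H2-K1 at 1.13 and Tap2 at 1.38. Cytotoxic T and NK cell genes had a median of 0.42 (22 of 24 positive, adjusted p = 0.000392, and adjusted p = 0.655 with an estimated correlation), and Gzmk, a granzyme gene, was called at 0.90 (adjusted p = 0.0371), also adjusted over the list alone. Checkpoint genes were higher by a median of 0.46 (all 14 positive, 1 adjusted over the list alone, Nt5e at 0.65), with Icos at 1.32 and Ctla4 at 1.29. Type I interferon genes (0.58), CD4 and regulatory T cells (0.28), macrophages and monocytes (0.23), neutrophils (0.44) and dendritic cells (0.27, 4 adjusted over the list alone, Ccr7 at 0.86) were higher as lists too. These lists had adjusted p-values of 7.3e-05 for checkpoints, 0.000392, 0.0114, 0.00549, 0.0195 and 0.00353, and adjusted p-values between 0.53 and 0.655 with an estimated correlation. Without parental IgG replicate 1 the interferon gamma median was 0.30 and the cytotoxic median 0.099, neither past the threshold. Type I interferon (0.13), CD4 and regulatory T cells (0.18), macrophages (0.13) and neutrophils (0.35) lost their calls without that array too. Without parental anti-PD-1 replicate 3 the calls ended for these 4 lists (0.29, 0.16, 0.008 and -0.063), and for neutrophils without parental IgG replicate 2 (0.41). Without both arrays that stood apart the interferon gamma and cytotoxic medians were 0.095 and 0.080, those of type I interferon, macrophages and neutrophils turned negative (-0.10, -0.070 and -0.065), and none of these immune lists was called.

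The endothelial list was higher and the oxidative phosphorylation list lower by camera in parental tumours given anti-PD-1, and both kept that call without both of those arrays. Xist, which female host cells express, was at 10.27 ± 0.51 against 9.41 ± 0.42 in this comparison (0.86, adjusted p = 0.0822), with every anti-PD-1 array above every IgG array. All 20 endothelial genes were positive, with a median of 0.57 (adjusted p = 3.08e-07, and adjusted p = 0.53 with an estimated correlation). Of these 0 were called over all genes and 13 adjusted over the list alone, including Egfl7 at 0.92, Aplnr at 1.11 and Pecam1 at 0.99. Oxidative phosphorylation genes had a median of -0.16 (adjusted p = 3.64e-06, and adjusted p = 0.53 with an estimated correlation). Of 25 genes 3 were lower, 8 adjusted over the list alone, among them Ndufa4 at -0.60, Atp5c1 at -0.41 and Atp5o at -0.36. Without both arrays the medians were 0.285 and -0.215. Fibroblast genes (median 0.26, adjusted p = 0.00549), hypoxia and glycolysis genes (0.24, 0.0114), mesenchymal state genes (0.15, 0.0211) and lipid uptake genes (0.21, 0.00549) were higher as lists, and cell cycle genes lower (-0.28, 0.00549, with Pcna at -0.46). The 3 Y-linked genes were lower as well (-0.69, 0.00739, with Uty at -0.70), a call that ended without both arrays (-0.405). With an estimated correlation these 6 lists had adjusted p-values between 0.53 and 0.664. The signs of the fibroblast and cell cycle medians turned without both arrays (-0.045 and 0.008). Without parental anti-PD-1 replicate 3 alone the calls ended for fibroblasts (0.077), hypoxia (0.075), mesenchymal state (0.17), lipid uptake (0.13) and cell cycle (0.025). Without parental IgG replicate 2 they ended for hypoxia (0.25) and cell cycle (-0.22).

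Fatty acid binding protein genes did not pass the test in parental tumours given anti-PD-1. Fabp4 differed by 1.78 (SE 0.95, adjusted p = 0.301), Fabp3 by 0.77 (0.506), Fabp5 by -0.25 (SE 0.20, 0.497), Fabp6 by -0.11, Fabp7 by 0.19, Fabp12 by -0.067 and Pmp2 by 0.043, with a list median of 0.043 (adjusted p = 0.833) that was -0.035 after centring each array. Parental IgG replicate 1, which stood apart, had the lowest Fabp4 (5.33) and Fabp3 (4.14) of the parental arrays and so raised both differences. Ferroptosis drivers and markers were higher as a list (median 0.10, adjusted p = 0.0401, adjusted p = 0.53 with an estimated correlation, and 0.0445 by fry), with Ptgs2 called, also adjusted over the list alone, and Hmox1 at 0.82 (adjusted p = 0.133). The call of this list ended without parental IgG replicate 1 or 2 (0.060 and 0.13) and without parental anti-PD-1 replicate 2 or 3 (0.090 and 0.14). In the ferroptosis defence list (median -0.077, adjusted p = 0.677) 3 of 21 genes were called, also adjusted over the list alone. These were Slc3a2, a subunit of the cystine transporter, at 0.53, Aifm2, an antioxidant reductase gene, at 0.39, and Nfe2l2, the gene of the antioxidant transcription factor NRF2, at -0.39 (with another probe set pointing the other way). Cd274 was at 8.24 ± 1.04 against 6.70 ± 0.87 (1.54, SE 0.55, adjusted p = 0.139), and Pdcd1 (0.41), Gpx4 (-0.13), Slc7a11 (0.46) and Acsl4 (0.060) did not pass.

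The lists not past the test in parental tumours were fatty acid oxidation (median -0.080, adjusted p = 0.0803, 2 lower adjusted over the list alone), fatty acid and sterol synthesis (-0.22, 0.0835), B and plasma cells (0.15, 0.151), mast cells (0.13, 0.545), adipocytes (0.10, 0.352), keratinocytes (0.33, 0.0595), nerve (-0.027, with a mean of 0.076, 0.955), red blood cells (-0.077, 0.875), epithelial tumour cells (-0.10, 0.48), lung lineage (-0.063, 0.247), and TGF-beta, Wnt and Notch targets (0.035, 0.346, with Ccn1 called at 1.04 and another of its probe sets pointing the other way). The comparison called 542 genes, all with groups that did not overlap, and 3399 (21.9%) had an unadjusted p under 0.05. Groups did not overlap for 3495 genes (22.6%, against 10% by chance). Leaving out parental IgG replicate 1, 2 or 3 gave 165, 11 or 9 genes, leaving out anti-PD-1 replicate 3 gave 57, leaving out anti-PD-1 replicate 1 gave 381 higher and 330 lower genes, leaving out both arrays that stood apart gave 100, and the muscle list as a covariate gave 61. A fit to these 6 arrays alone gave 0 genes, and array weights gave 918. Of the 30 named genes called, 3 (Fosb, Nav2 and Mia) kept the call whichever array was left out.

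**Figure D3:**
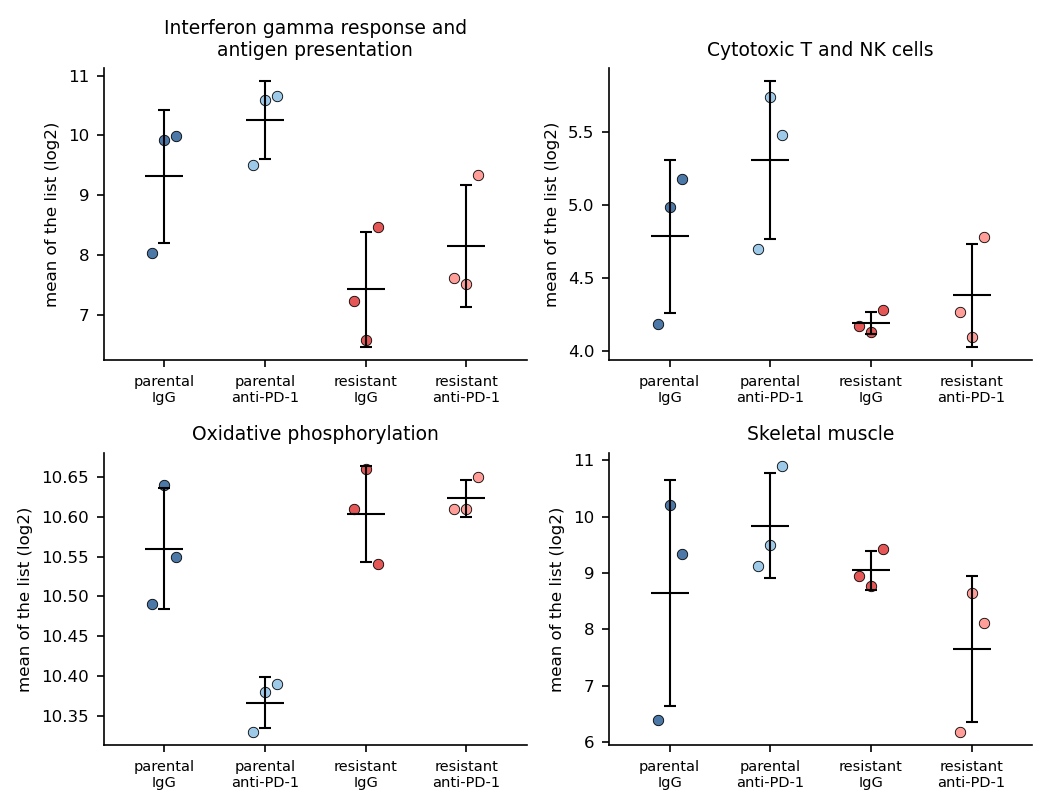
Mean log2 level of the interferon gamma and antigen presentation, cytotoxic T and NK cell, oxidative phosphorylation and skeletal muscle lists on each array, by group; points are arrays, the dash is the mean and the bar the SD (n = 3). The interferon gamma list averaged 9.32, 10.25, 7.42 and 8.16 and oxidative phosphorylation 10.56, 10.37, 10.61 and 10.63 in parental IgG, parental anti-PD-1, resistant IgG and resistant anti-PD-1 tumours.

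Resistant tumours given anti-PD-1 were compared with those given IgG to ask what the treatment changed in the resistant line. No gene passed the adjusted p of limma, and 738 (4.76%) had an unadjusted p under 0.05. The smallest p-values among lower genes belonged to Ppbp, the gene of a platelet and neutrophil chemokine, at -1.56 (SE 0.19, adjusted p = 0.0628), from 6.06 ± 0.37 to 4.50 ± 0.08, Hs6st2, a heparan sulfate enzyme gene, at -1.30 (0.394), and the glucose transporter gene Slc2a3 at -0.95 (0.896). Among higher genes they belonged to Zfp605 at 0.59 (adjusted p = 0.853), Tex29 at 0.44 and Ccdc88c at 0.30 (both 0.896, the latter with another probe set pointing the other way). None of the fixed genes passed, with adjusted p-values of 0.896 or more. Fabp4 differed by -1.46 (SE 0.95), Fabp7 by 1.19, Fabp3 by -0.72, Fabp5 by -0.32, Fabp6 by 0.10, Fabp12 by 0.027, Pmp2 by -0.13, Pdcd1 by -0.11, Cd274 by 0.070, Gpx4 by 0.040, Slc7a11 by -0.017 and Acsl4 by 0.12.

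Lists passed camera with the preset correlation in resistant tumours, but 0 passed with an estimated correlation (lowest adjusted p = 0.497) or by fry, and no single gene did. Interferon gamma and antigen presentation genes were higher, with a median of 0.56 and all 29 positive (adjusted p = 0.000803, and adjusted p = 0.768 with an estimated correlation), including Iigp1 at 1.79, Gbp6 at 1.67 and Igtp at 1.22. The call was lost without resistant IgG replicate 2 (median 0.31) and without resistant anti-PD-1 replicate 3 (0.15). Stromal and host tissue lists were lower: fibroblasts and matrix (median -0.52), endothelial cells (-0.33, all 20 negative), adipocytes (-0.64, all 15 negative), skeletal muscle (-1.58, all 19 negative), mesenchymal state (-0.14) and red blood cells (-0.14). Their adjusted p-values were 2.59e-08, 1.81e-06, 1.19e-07, 1.42e-07, 0.00717 and 0.0168, and each had adjusted p = 0.497 with an estimated correlation. Single arrays moved the medians of adipocytes (-0.093 without resistant IgG replicate 2), muscle (-0.735 without anti-PD-1 replicate 1) and fibroblasts (-0.28 without anti-PD-1 replicate 3). Examples are Pdgfrb and Thy1 at -0.53, Emcn at -0.69, Adipoq at -2.33 and Actn3 at -1.96. Leaving out single resistant arrays ended the call for endothelial cells (-0.15 without IgG replicate 3), mesenchymal state (-0.092 and -0.12 without replicate 3 of IgG or of anti-PD-1) and red blood cells (-0.11 without IgG replicate 2, -0.14 without anti-PD-1 replicate 1).

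Myeloid, lipid and hypoxia lists were lower in resistant tumours given anti-PD-1. The medians were -0.24 for lipid uptake and droplets, -0.17 for hypoxia and glycolysis, -0.15 for B and plasma cells, -0.24 for macrophages and monocytes, -0.43 for neutrophils, -0.11 for dendritic cells and -0.29 for mast cells. Their adjusted p-values were 0.000797, 1.42e-07, 0.000797, 4.36e-05, 6.31e-06, 0.019 and 0.0188, and with an estimated correlation the adjusted p was 0.587 for macrophages, 0.676 for mast cells and 0.497 for each of the others. Adjusted over the list alone, 1 hypoxia gene and 1 dendritic cell gene passed. Examples are G0s2 at -1.84, Adm at -1.07, Cd163 at -0.94 and Cxcl2 at -1.78, each with adjusted p = 0.896. The call ended without resistant IgG replicate 2 for lipid uptake (-0.045) and without resistant IgG replicate 3 for macrophages (-0.032). For dendritic cells it ended without that array (-0.13) or anti-PD-1 replicate 1 (-0.10), and for mast cells without IgG replicate 1 or 2 (-0.31 and -0.14) or anti-PD-1 replicate 1 or 2 (-0.20 and -0.17).

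The lists not past the test in resistant tumours were fatty acid binding proteins (median -0.13, adjusted p = 0.495), ferroptosis defence (0.063, 0.419), ferroptosis drivers and markers (0.017, 0.931), fatty acid oxidation (0.043, with a mean of -0.025, 0.656), fatty acid and sterol synthesis (0.043, 0.805), oxidative phosphorylation (0.020, 0.805), cell cycle (0.012, 0.805), cytotoxic T and NK cells (0.15, 0.601), CD4 and regulatory T cells (-0.058, 0.126), checkpoints (0.012, 0.849), type I interferon (0.23, 0.387), keratinocytes (0.013, 0.647), nerve (0.10, 0.849), epithelial tumour cells (0.063, 0.849), lung lineage (0.043, 0.805), Y-linked genes (-0.14, 0.19), and TGF-beta, Wnt and Notch targets (0.030, 0.601). In 7 of the 31 lists the direction of the set test, which compares a list with all other genes, differed from the sign of the median. Groups did not overlap for 2201 genes (14.2%, against 10% by chance), and 0 of these were called. The fit with the replicate number as a block also called 0 genes, and leaving out resistant IgG replicate 2 gave 1.

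Resistant and parental tumours given anti-PD-1 were compared to ask how the lines differ under the treatment. Cd274, the gene of PD-L1, was lower in resistant tumours at 5.33 ± 0.74 against 8.24 ± 1.04 (SD, n = 3), a difference of -2.91 (SE 0.55, adjusted p = 0.00255). Fosb was lower at -3.42 (SE 0.31, adjusted p = 7.11e-05), Cdkn2a by -3.47 (SE 0.25, adjusted p = 2.92e-05), and the Y-linked genes Eif2s3y, Kdm5d and Uty by -4.68, -3.65 and -1.60. Higher genes included Ambp at 3.66 (SE 0.22, adjusted p = 1.32e-05), the albumin gene Alb at 2.64 (SE 0.58, adjusted p = 0.0056) and the tight junction gene Cldn9 at 3.55 (SE 0.31, adjusted p = 6.03e-05). In all, 3343 genes were higher and 1843 lower in resistant tumours, 306 and 389 of them by at least 2-fold. The mean of the interferon gamma list was 8.16 ± 1.02 against 10.25 ± 0.65, that of the muscle list 7.64 ± 1.30 against 9.84 ± 0.94, the Gapdh difference between the ends 0.033 ± 0.055 against 0.32 ± 0.09, and Xist was at 8.61 ± 0.13 against 10.27 ± 0.51.

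The other genes with the largest differences under anti-PD-1 were, on the higher side, Cym (3.20), Smim31 (3.11), Tm4sf4 (2.88), Gspt2 (2.45), Tmprss11e (2.42), the neuritin gene Nrn1 (2.41) and the splicing regulator gene Mbnl3 (2.39). On the lower side they were Cacna1h (-3.36), Cftr (-3.07), Gzmg (-3.08) and the interferon-induced GTPase genes Gbp8 (-3.35), Gbp3 (-3.33) and Gbp6 (-3.24). The line differences overlapped between the treatments, which share no arrays. Of the 1384 genes higher in resistant tumours under IgG 971 (70.2%) were also higher under anti-PD-1, against 298.6 for independent lists, and of the 1133 lower genes 733 (64.7%) were also lower, against 134.8. Only 3 and 2 genes were called in opposite directions.

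Fabp5 was lower in resistant tumours under anti-PD-1 as well, at 9.46 ± 0.30 against 10.64 ± 0.21 (-1.18, SE 0.20, adjusted p = 0.00126), and Fabp7, a carrier of brain and some tumours, was higher at 5.36 ± 1.31 against 3.13 ± 0.08 (2.23, SE 0.53, adjusted p = 0.00847). Fabp6, the ileal bile acid carrier gene, was higher by 0.33 (adjusted p = 0.0184), but both levels, 3.42 ± 0.13 and 3.09 ± 0.06, lay near the dim filter of 3.32. Its call was lost without resistant anti-PD-1 replicate 2 or 3 (0.29 and 0.30). Fabp4 (-0.45, adjusted p = 0.749), Fabp3 (-1.05, 0.213), Fabp12 (0.10, 0.43) and Pmp2 (-0.16, 0.388) did not pass. The list, with 2 genes higher and 1 lower, also adjusted over the list alone, had a median of -0.16 (adjusted p = 0.668), which was 0.077 after centring each array. Among the fixed genes of ferroptosis, Gpx4 was higher by 0.38 (SE 0.09, adjusted p = 0.00709) and Acsl4 lower at -0.43 (adjusted p = 0.0155), while Slc7a11 did not pass (-0.54, 0.164). The Acsl4 call was lost without parental anti-PD-1 replicate 2 (-0.34) or resistant anti-PD-1 replicate 3 (-0.40). Pdcd1 was lower at -0.80 (adjusted p = 0.0437), with groups that overlapped, and the call held only where parental anti-PD-1 replicate 1 was left out (-1.13), with values from -0.45 to -0.89 without any other single array.

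**Figure D4:**
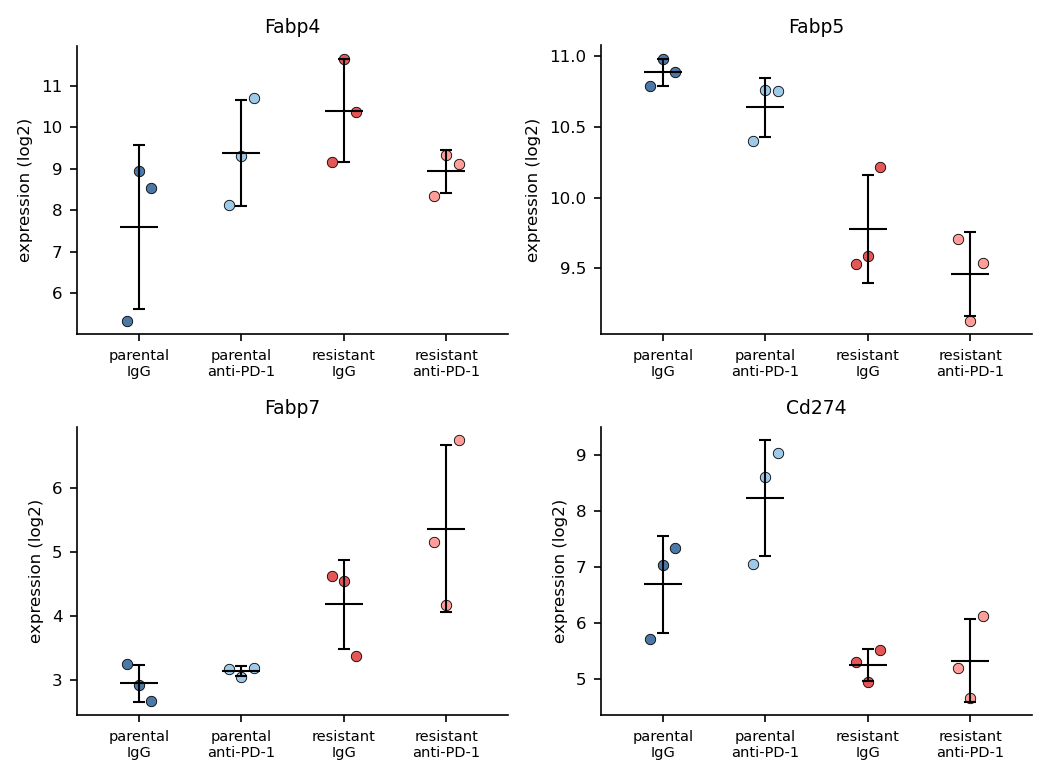
Log2 expression of Fabp4, Fabp5, Fabp7 and Cd274 on each array, by group; points are arrays, the dash is the mean and the bar the SD (n = 3). Fabp5 averaged 10.89 and 10.64 in parental and 9.78 and 9.46 in resistant tumours, and Cd274 averaged 6.70, 8.24, 5.26 and 5.33 in parental IgG, parental anti-PD-1, resistant IgG and resistant anti-PD-1 tumours.

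Ferroptosis and lipid genes differed between the lines under anti-PD-1. Ferroptosis drivers and markers were lower as a list (median -0.16, adjusted p = 0.0181, and adjusted p = 0.311 with an estimated correlation). Of 23 genes 2 were higher and 6 lower, the same numbers adjusted over the list alone, with Cybb, a subunit of the phagocyte oxidase, at -2.12, the transferrin receptor gene Tfrc at -0.65 (another probe set pointed the other way) and Pebp1 at 0.56. In the defence list 7 of 21 genes were higher and 2 lower, the same numbers adjusted over the list alone (median 0.24, adjusted p = 0.359, and 0.0128 by fry), with Dhodh at 1.11, Hspb1 at 1.06 and Gch1 at 0.94. Fatty acid oxidation genes were higher (median 0.42, adjusted p = 0.00179, and adjusted p = 0.515 with an estimated correlation). Of 19 genes 11 were called, 14 adjusted over the list alone, including Cpt2 at 0.56, Etfa at 0.68 and Acaa2 at 0.81. Lipid uptake and droplets (-0.16, adjusted p = 0.162, 3 of 21 lower, 2 adjusted over the list alone, with Dgat1 at -0.73) and fatty acid and sterol synthesis (0.23, 0.973, 2 higher and 2 lower, with Me1 at -0.82) did not pass as lists.

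Cell cycle and oxidative phosphorylation lists were higher, and the hypoxia list lower, in resistant tumours under anti-PD-1. Cell cycle genes had a median of 0.79 with all 26 positive (adjusted p = 1.82e-05, and adjusted p = 0.626 with an estimated correlation). Of these 16 were called and 24 adjusted over the list alone, including Mcm5 at 1.45 and Cdk1 at 0.98, and the median was 0.44 without parental anti-PD-1 replicate 3. Oxidative phosphorylation genes had a median of 0.27 (adjusted p = 0.000725, and adjusted p = 0.515 with an estimated correlation). Of 25 genes 12 were called and 14 adjusted over the list alone, including Atp5a1 at 0.59. Hypoxia and glycolysis genes had a median of -0.41 (adjusted p = 1.21e-05, and adjusted p = 0.515 with an estimated correlation). Of 21 genes 10 were lower and 1 higher, 11 and 1 adjusted over the list alone, including Hk2 at -1.78 and Vegfa at -0.82.

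Interferon, T cell, checkpoint, dendritic cell and mast cell lists were lower in resistant tumours under anti-PD-1. In the interferon gamma and antigen presentation list all 29 genes were negative (median -2.08) and 22 were called, 26 adjusted over the list alone, among them Tapbp (-1.71), Cd74 (-1.89), Tap2 (-1.91) and H2-Ab1 (-1.68). In the cytotoxic T and NK cell list (median -0.82) 10 of 24 were lower, 15 adjusted over the list alone, with Gzmb at -2.21 and Ifng at -1.66. Checkpoint genes (-0.61, 8 of 14 lower, also 8 adjusted over the list alone) included Ctla4 at -1.75 and Icos at -1.56. Type I interferon genes (-1.25, 12 of 25 lower, 16 adjusted over the list alone), CD4 and regulatory T cells (-0.36, 4 of 12), dendritic cells (-0.23, 4 of 13) and mast cells (-1.08, 5 of 9, 6 adjusted over the list alone) were lower too, with Stat2 at -1.48, Il7r at -1.78, Itgax at -1.44 and Tpsab1 at -1.67. The adjusted p-values of the 7 lists were 6.41e-10, 1.91e-05, 2.98e-05, 3.48e-07, 0.00224, 0.00203 and 0.000725 in that order, and adjusted p = 0.515 for each with an estimated correlation. By fry the interferon gamma list had an adjusted p of 0.0476, and all 7 lists stayed past the threshold by camera without the arrays that stood apart, with medians of -0.39 for checkpoints and -0.83 for type I interferon.

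Stromal and myeloid lists under anti-PD-1 depended on parental anti-PD-1 replicate 3. Macrophages and monocytes (median -0.30, 4 of 25 lower and 1 higher, adjusted p = 0.032), neutrophils (-0.46, 3 of 18 lower and 1 higher, 0.0208) and fibroblasts (-0.21, 2 of 23 lower, 0.0483) were lower, with adjusted p = 0.65 for each with an estimated correlation, and had medians of 0.058, 0.15 and 0.13 without that array. Endothelial genes were lower (-0.31, 3 of 20, adjusted p = 0.0041, and adjusted p = 0.632 with an estimated correlation), with Flt1 at -0.72, but the median was -0.050 without that array, no longer past the threshold. Without resistant anti-PD-1 replicate 2 the macrophage and neutrophil calls ended (-0.10 and -0.35), as did the fibroblast call without resistant anti-PD-1 replicate 3 (-0.093). Skeletal muscle genes were lower (-2.18, all 19 negative, adjusted p = 2.46e-05, and adjusted p = 0.542 with an estimated correlation), with 3 called, 0 adjusted over the list alone, and Myh2 at -2.24. The 3 Y-linked genes were lower with a median of -3.65 (adjusted p = 4.92e-06, and adjusted p = 0.206 with an estimated correlation). B and plasma cells (-0.080, adjusted p = 0.231), adipocytes (0.067, with a mean of -0.002, 0.88), keratinocytes (-0.11, with a mean of 0.025, 0.668), nerve (0.17, 0.421), red blood cells (-0.060, 0.744), epithelial tumour cells (-0.098, 0.131), lung lineage (-0.17, 0.193), mesenchymal state (-0.020, 0.145), and TGF-beta, Wnt and Notch targets (0.17, 0.668) did not pass. Called members included S100b (1.15), Ocln (-2.77), Sftpd (-1.14), Foxa1 (0.83) and Ccn1 (-1.51).

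The comparison between the lines under anti-PD-1 called 5186 genes, and 6832 (44.1%) had an unadjusted p under 0.05. Groups did not overlap for 7074 genes (45.7%, against 10% by chance), 5042 of them called. Centring each array on its median moved the median of all genes from 0.073 to 0.18 and the split to 5075 higher and 1299 lower genes, so the smaller differences above are to be read against a shift of that size. The size is a lower limit where the level of 1 line lay below the dim filter of 3.32, in resistant tumours for Eif2s3y, Kdm5d, Uty, Gzmg, Cftr and Pdcd1 (2.09 to 3.18) and in parental tumours for Cldn9, Tmprss11e and Fabp7 (2.44 to 3.28). For Fabp6 both levels, 3.42 and 3.09, lay near that filter, so its difference cannot be told apart from background. With the muscle list as a covariate 3181 genes were called. Of the 95 named genes called, 66 kept the call whichever array was left out.

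The interaction asked whether anti-PD-1 acted differently in the lines, as the effect in resistant minus that in parental tumours. No gene passed the adjusted p of limma, and 2713 (17.5%) had an unadjusted p under 0.05. The smallest p-values, each with adjusted p = 0.101, belonged to Fosb (-2.91, SE 0.43), Atf3 (-1.90) and Nav2 (-1.37) on the lower side, and to Exph5 (1.10), Zfp606 (1.39) and the histone gene H3f3b (0.91) on the higher side. Other probe sets of Nav2 and Zfp606 pointed the other way. Fabp4 differed by -3.24 (SE 1.34, adjusted p = 0.252), Cd274 by -1.47 (0.346), Fabp3 by -1.49 (0.387), Fabp7 by 1.00 (0.501), Fabp5 by -0.070 (0.916), Fabp6 by 0.21, Fabp12 by 0.093, Pmp2 by -0.18, Pdcd1 by -0.52, Gpx4 by 0.17, Slc7a11 by -0.48 and Acsl4 by 0.063. Of the 542 genes called in parental tumours 226 (41.7%) had the same sign in resistant tumours, against 6561 (42.3%) of all genes tested. Without parental anti-PD-1 replicate 1 the interaction called 78 genes (23 higher and 55 lower), without parental IgG replicate 3 it called 1, with array weights 121 (79 higher and 42 lower), with the replicate number as a block 3 (0 higher and 3 lower), and with every probe set on its own 2.

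Between the lines the effect of anti-PD-1 differed in 17 of the 31 lists by camera, 2 toward higher and 15 toward lower in resistant tumours, and in 0 with an estimated correlation (lowest adjusted p = 0.408) or by fry. Endothelial cells (median -0.97, adjusted p = 2.67e-10, 14 genes adjusted over the list alone), fibroblasts (-0.78, 6.48e-07) and skeletal muscle (-2.67, 6.48e-07) had the smallest adjusted p-values, each 0.408 with an estimated correlation, and these 3 lists stayed past the threshold without both arrays that stood apart (-0.54, -0.31 and -0.89). Without both arrays 8 of the 17 calls ended, those of cell cycle (-0.001), type I interferon (0.28), cytotoxic cells (-0.019), CD4 and regulatory T cells (-0.165), checkpoints (-0.34), B and plasma cells (-0.10), macrophages (-0.12) and neutrophils (-0.35). Single arrays also ended the calls of cytotoxic cells (-0.043 without parental IgG replicate 1, -0.035 or -0.23 without parental anti-PD-1 replicate 2 or 3, -0.21 without resistant anti-PD-1 replicate 2), cell cycle (0.004 to 0.336 over 5 such fits) and type I interferon (-0.302 to 0.063 over 6). Oxidative phosphorylation differed by 0.23 (adjusted p = 3.26e-05, 0.408 with an estimated correlation, 3 genes adjusted over the list alone) and by 0.24 without both arrays. The lists not past the test were fatty acid binding proteins (-0.070, adjusted p = 0.526), ferroptosis defence (0.17, 0.415), ferroptosis drivers (-0.023, 0.0911), fatty acid synthesis (0.29, 0.101), interferon gamma (-0.22, 0.0976), fatty acid oxidation (0.14), mast cells (-0.40), keratinocytes (-0.30), nerve (0.087), red blood cells (-0.17), epithelial tumour cells (0.085), lung lineage (0.037), Y-linked genes (0.45), and TGF-beta, Wnt and Notch targets (-0.062).

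Called differences between the lines were unevenly spread over the chromosomes. Of all called genes 55.0% were higher in resistant tumours under IgG and 64.5% under anti-PD-1. Under control IgG 230 genes of chromosome 8 were higher and 13 lower in resistant tumours, and on chromosome 4 156 were higher and 27 lower. On chromosome 6 24 were higher and 145 lower, and on chromosome 15 24 and 114. Under anti-PD-1, on other arrays, the counts were 369 and 38 for chromosome 8, 292 and 76 for chromosome 4, 80 and 144 for chromosome 6, and 57 and 135 for chromosome 15. Chromosomes were examined after these values were seen.

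**Figure D5:**
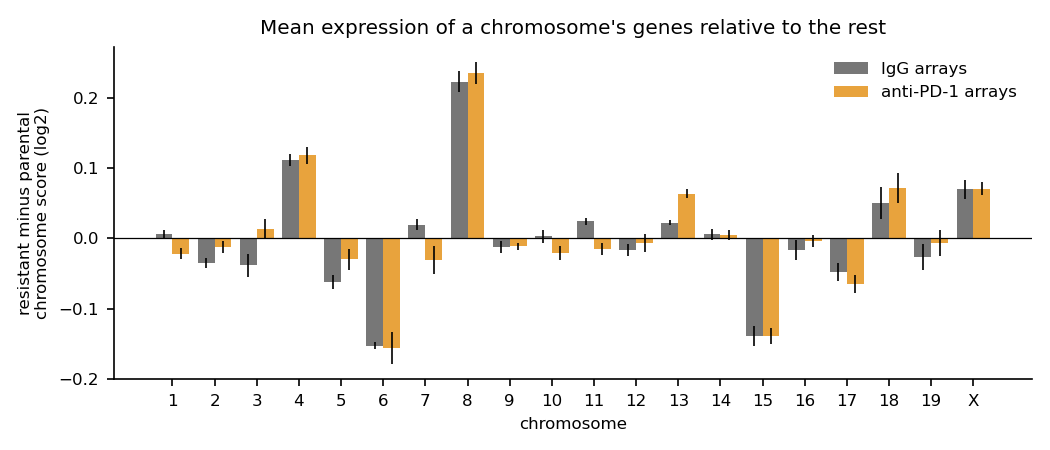
Chromosome score, resistant minus parental, for 20 chromosomes, as bars from 0 in log2 units, from the IgG arrays in grey and the anti-PD-1 arrays in orange; each bar is a difference between means of 3 arrays and its line the standard error. Over all 12 arrays chromosome 8 differed by 0.229 and chromosome 6 by -0.154.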

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

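The tests on Y-linked genes, on copy number, on brightness in the middle and upper range, on the arrays that stand apart, on muscle and on handling were chosen after the results they measure were seen. Those on cell composition and on brightness in general were set before their own results, although chromosomes were examined only after the differences between the lines were seen.

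The effect of anti-PD-1 differed between the lines, by a test of the interaction with a preset correlation, for 17 lists. The medians, resistant minus parental effect, were -0.457 for lipid uptake and droplets, 0.227 for oxidative phosphorylation, -0.433 for hypoxia and glycolysis, 0.345 for cell cycle and -0.25 for mesenchymal state. Among immune lists they were -0.272 for cytotoxic T and NK cells, -0.342 for CD4 and regulatory T cells, -0.485 for checkpoints, -0.317 for type I interferon, -0.303 for B and plasma cells, -0.45 for macrophages and monocytes, -0.895 for neutrophils and -0.387 for dendritic cells. Among stromal lists they were -0.783 for fibroblasts and matrix, -0.965 for endothelial cells, -0.893 for adipocytes and -2.673 for skeletal muscle. The adjusted p-values ran from 2.67e-10 for endothelial cells to 0.0388 for cell cycle, and with an estimated correlation from 0.408 to 0.672. In 14 of the lists the effect in parental tumours and that in resistant tumours had opposite signs, for example 0.572 and -0.33 for endothelial cells and 1.263 and -1.58 for skeletal muscle. Without the pair of parental arrays that stood apart 8 of the 17 calls ended, listed with the interaction above.

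Splits of the 6 arrays of a comparison number 10, too few for a share under 0.05. The real split called 2517 genes between the lines under IgG (highest other split 1), 542 for anti-PD-1 in parental tumours (highest other 1), 0 for anti-PD-1 in resistant tumours (highest other 0) and 5186 between the lines under anti-PD-1 (highest other 0), so that 1, 1, 10 and 1 of the 10 splits gave as many. For the interaction the real split called 0 genes and the highest other of 100 drawn out of 200 called 2. Where the real split called 0 genes every split gives as many (100 of 100 here), so the count decides nothing.

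The Y-linked genes Eif2s3y, Kdm5d and Uty were lower in every resistant than in every parental array, with a median of -2.88 over the 4 Y-linked genes above the median of all probe sets. A smaller share of tumour cells in resistant tumours would lower epithelial tumour cell genes alike, but their median was -0.133 over 18 genes. More host cells from the female mice would raise Xist, but Xist differed by -1.047 (exact p = 0.00649), lower in resistant tumours. Loss of the Y chromosome, or of its expression, in the resistant line may account for the pattern, with 3 of these 4 genes lower in all resistant arrays, but it cannot be told apart from other changes, because Sry, the remaining one of the 4, was at 4.98 in parental and 4.88 in resistant tumours given IgG, close to the bound of 4.8, and no value shows whether this is signal of the gene or background. The line itself, which the design names, stays open as well.

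Between the lines, called genes of chromosomes 8 and 4 were mostly higher and those of chromosomes 6 and 15 mostly lower in resistant tumours, with scores that differed by 0.229, 0.115, -0.154 and -0.139 (exact p = 0.00216 each, adjusted p = 0.00722, over 12 arrays). These p-values do not set the chromosomes apart. By the same exact test chromosomes 13 (0.043) and X (0.070) had equal values. The scores of chromosomes 5, 17 and 18 (adjusted p = 0.00962 each) and 2 (0.0216) passed as well. For chromosome 8, tissue content as it varied among the 6 parental arrays does not account for the shift. The score ranged over only 0.0492 across these arrays, although their tissue content varied widely. The ranges for chromosomes 4, 6 and 15 were 0.038, 0.073 and 0.058, also smaller than their score differences. A change in cell composition found only between the lines is not covered. An example is the adipocyte list under IgG, at 5.25 to 6.94 in resistant and 4.51 to 4.87 in parental tumours. Brightness of the probe sets does not account for the chromosome 8 shift among genes of middle and high brightness. There 91.8605% and 99.2593% of called chromosome 8 genes were higher, against 48.95% and 44.74% on the other chromosomes. For the lowest range it cannot be told apart, with 77.2727% of only 22 called genes (17 and 5) against 68.54% (Fisher's exact test, p = 0.483). Copy number differences between the lines cannot be told apart from other stable differences between them. The 20 chromosome scores from the IgG arrays and from the anti-PD-1 arrays, which share none, had a Spearman correlation of 0.699 (Pearson 0.951, permutation p = 8e-04), which either would give, and no DNA was measured.

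Immediate early genes were higher in parental tumours given anti-PD-1, with a median of 0.653 over the 32 genes and 17 called. The arrays that stand apart are not the whole cause of the median, since it was 0.600 without both, nor is muscle, since it was 0.633 with the muscle list as a covariate, but only 5 and 7 of the genes were then called. Handling or ischaemia of the tumours before RNA preparation may raise such genes and cannot be told apart from a response to the antibody, because the labels give no order or time of collection. In resistant tumours the same genes had a median of -0.062 with 11 of 32 positive, which leaves handling of the treated parental tumours alone open. A response of parental tumours to anti-PD-1, which the design names, stays among the open explanations.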

How the results depend on the processing

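The fits without both parental arrays that stood apart (parental IgG replicate 1 and parental anti-PD-1 replicate 3) and with the muscle list as a covariate were chosen after the results were seen, and all other settings before. Signal over background limits the dim genes, since the resistant levels of Cdkn2a, Cftr, Gzmg and the Y-linked genes and the parental levels of Fabp7, Fabp6 and Tmprss11e lie near or below the filter, and with 3 arrays per group single arrays moved the counts. Of 188 calls of named genes, 186 were kept with quantile normalization, 183 with centring, 186 without a filter, 181 of 181 with a filter at the median, 171 with the mean of the probe sets, 187 with every probe set on its own, 140 with only the compared groups, 175 with trend and robust, 181 with array weights, 183 with the replicate block and 123 at 2-fold. None of these calls changed direction, in any of these settings or without any single array. Of 79 list calls made with a preset correlation, 0 were kept with an estimated correlation and 15 by fry, 76 with quantile normalization, 77 with centring, 78 without a filter, 71 of 78 with a filter at the median, 75 both with the mean of the probe sets and with every probe set, 62 of 62 with only the compared groups, 79 with trend and robust, 61 with array weights and 78 with the block. Without both parental arrays 25 of 53 list calls were kept and 11 changed direction. The cause was not tested. Fewer arrays or smaller fits leave fewer degrees of freedom, and stricter filters fewer genes. Yet with only the compared groups 2368 genes were called between the lines under IgG and 3975 under anti-PD-1. The main fit assumes equal variance in all groups.

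For anti-PD-1 in parental tumours, where 542 genes were called, 0 were called with only the compared groups, 918 with array weights, 50 at 2-fold, 100 without both parental arrays and 61 with the muscle covariate, and between 9 and 711 without any single array. Between the lines under IgG, with 2517 genes, 5152 were called with array weights, 368 at 2-fold, and 1273 to 2269 without any single array. For anti-PD-1 in resistant tumours, with 0 genes, 1 was called with trend and robust, 1 with array weights, and 0 to 1 without any single array. Between the lines under anti-PD-1, with 5186 genes, 695 were called at 2-fold, 3181 with the muscle covariate and 3826 to 5043 without any single array. For the interaction, with 0 genes, 2 were called with every probe set on its own (2 higher and 0 lower), 121 with array weights (79 higher and 42 lower), 3 with the replicate block (0 higher and 3 lower), and 0 to 78 without any single array, the 78 being 23 higher and 55 lower. The array weights ran from 0.234 (parental anti-PD-1 replicate 3) to 2.926. With the block 2858, 725, 0 and 5601 genes were called between groups, in the order of the report. Equal numbers best matched each other in 27 of 36 comparisons of arrays, and between the parental groups same-numbered arrays deviated together at 0.636, 0.057 and 0.44, a hint from the data and not from the design.

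The following values, single genes and lists, changed direction. With quantile normalization Fabp12 was -0.043 between the lines under IgG and Slc7a11 0.013 for anti-PD-1 in resistant tumours, which centring put at 0.010. The fatty acid binding protein list was -0.035, 0.077 and 0.062 with centring and -0.068, 0.098 and 0.052 without a filter, for anti-PD-1 in parental tumours, between the lines under anti-PD-1 and for the interaction. The driver list was 0.027 for the interaction with centring, and the dendritic cell list 0.007 for anti-PD-1 in resistant tumours with a filter at the median. With the mean of the probe sets, Slc7a11 was 0.102 and the driver list -0.006 between the lines under IgG, Acsl4 -0.036 and the driver list -0.035 for anti-PD-1 in resistant tumours, and for the interaction Fabp5 was 0.26, Acsl4 -0.053, the fatty acid binding protein list 0.093 and the driver list 0.001. With every probe set on its own, Slc7a11 was 0.263 and the driver list -0.023 between the lines under IgG, Acsl4 -0.18 for anti-PD-1 in resistant tumours, and for the interaction Fabp5 was 0.59 and Acsl4 -0.303.

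With array weights the defence list was 0.005 and cell cycle 0.001 for anti-PD-1 in parental tumours, Fabp12 -0.016 and Slc7a11 0.047 in resistant tumours, fibroblasts 0.044 between the lines under anti-PD-1, and for the interaction Fabp5 0.102, Acsl4 -0.037 and the fatty acid binding protein list 0.101. Without both parental arrays, for anti-PD-1 in parental tumours, the lists were -0.075 for fatty acid binding proteins, 0.008 for cell cycle, -0.10 for type I interferon, -0.070 for macrophages, -0.065 for neutrophils, -0.045 for fibroblasts and -0.555 for muscle. Between the lines under anti-PD-1 they were 0.153 for fatty acid binding proteins, 0.058 for macrophages, 0.147 for neutrophils and 0.133 for fibroblasts, and for the interaction 0.035 for fatty acid binding proteins, -0.001 for cell cycle and 0.278 for type I interferon.

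Leaving out single arrays gave ranges that crossed 0. Between the lines under IgG they were -0.197 to 1.083 for Fabp3, -0.033 to 0.062 for Fabp12, -0.11 to 0.118 for Pmp2, -0.265 to 0.065 for Slc7a11 and -0.007 to 0.073 for drivers. For anti-PD-1 in parental tumours they were -0.047 to 0.148 for Pmp2, -0.038 to 0.192 for Acsl4, and for lists -0.047 to 0.137 for fatty acid binding proteins, -0.552 to 0.025 for cell cycle, -0.063 to 0.807 for neutrophils and -0.088 to 2.045 for muscle. Between the lines under anti-PD-1 they were -1.073 to 0.212 for Fabp4, and for lists -0.243 to 0.153 for fatty acid binding proteins, -0.652 to 0.058 for macrophages, -0.817 to 0.147 for neutrophils and -0.475 to 0.133 for fibroblasts. In resistant tumours they were -0.047 to 0.098 for Fabp12, -0.327 to 0.403 for Cd274, -0.003 to 0.092 for Gpx4, -0.115 to 0.155 for Slc7a11 and -0.018 to 0.04 for drivers, and 0.147 to 0.887 for interferon gamma, whose test turned while its median stayed positive. For the interaction they were -0.195 to 0.15 for Fabp5, -0.068 to 0.162 for Acsl4, -0.178 to 0.095 for fatty acid binding proteins, -0.06 to 0.013 for drivers and -0.612 to 0.063 for type I interferon, while cell cycle ran from 0.004 to 0.577 and its test turned.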

Other observations

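All genes and lists in this part were chosen after their values were seen, and so were their tests. Immediate early genes beyond Fosb and Atf3 were higher in parental tumours given anti-PD-1. Of 32 immediate early genes, transcription factors and signalling genes induced within minutes of a stimulus, 30 were positive, with a median of 0.65, and 17 were called, or 27 adjusted over the list alone. The list was drawn up after some of its members were seen to be higher, so its p-values (adjusted p = 0.00171 with an estimated correlation, adjusted over the added lists alone) are no independent test and cannot be ranked against those of the lists fixed in advance. In resistant tumours the median was -0.062 with 0 genes called by limma (adjusted p = 0.595 with an estimated correlation), and the interaction had a median of -0.67 with all 32 negative, 18 of them adjusted over the list alone (adjusted p = 0.00259 with an estimated correlation). Between the lines the list had a median of -0.66 with 21 lower genes under anti-PD-1 and of -0.077 with 1 higher and 5 lower under IgG. The median effect in parental tumours lay between 0.58 and 0.75 without any single parental array, but the number of called genes fell to 2 and 3 without parental IgG replicate 2 and 3, to 7 without parental anti-PD-1 replicate 3 and to 10 without parental IgG replicate 1.

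Genes of mitochondrial ribosomal proteins, which translate the transcripts of the mitochondrial genome, were likewise listed after the values were seen. Of 76 genes 11 were lower in parental tumours given anti-PD-1, 45 adjusted over the list alone, with a median of -0.28 (adjusted p = 7.59e-20 by camera, and adjusted p = 0.0515 with an estimated correlation). The list mean ran from 8.15 to 8.28 under anti-PD-1 and from 8.43 to 8.55 under IgG. In the same arrays Xist was at 10.27 ± 0.51 against 9.41 ± 0.42 and the mean of the Y-linked genes at 6.03 ± 0.28 against 6.61 ± 0.17, so a change in host cell content is not excluded. Their median was 0.047 in resistant tumours, and the interaction had a median of 0.35 with 21 higher genes adjusted over the list alone (adjusted p = 0.0655 with an estimated correlation). Under anti-PD-1 55 genes were higher in resistant than in parental tumours, 61 adjusted over the list alone, with a median of 0.47 (adjusted p = 0.0869 with an estimated correlation). Under IgG 11 were higher and 3 lower, with a median of 0.13.

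On chromosome 4 Cdkn2a and Cdkn2b, next to each other, were lower in resistant tumours, and none of the neighbouring genes examined on either side was lower past the test. Mtap, which encodes an enzyme of methionine salvage and is the nearest tested gene on one side, was higher in resistant tumours by 1.33 under IgG (SE 0.26, adjusted p = 0.00776) and by 2.02 under anti-PD-1 (adjusted p = 0.000352). On the other side of Cdkn2a and Cdkn2b, Elavl2 differed by -0.060 and 0.23, while Tusc1 (0.72 and 0.77) and Caap1 (0.51 and 0.93) were higher under both antibodies. The level of Cdkn2a in resistant tumours, 3.29 and 3.79, lay near the 25th percentile of all values (3.32), that of Cdkn2b at 5.92 and 6.04 did not, and host cells in the whole tumours express both genes to an unknown degree. Whether the locus is deleted was not tested, since no DNA was measured.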
